A study of Mus musculus with 3 samples.

How the data were processed

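RNA from 3 lines of FSP1-positive mouse forestomach fibroblasts, grown to subconfluency in serum-containing medium at low passage, was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per line, per the labels' protocols. On this array each transcript is read by probes from exons spread along the gene, and the values are at transcript level, per the labels' protocols. The labels describe the mice as a mix of C57BL6 and BALBc of either sex, without assigning a strain or a sex to a line. The groups were wild type, Tgfbr2 cKO and Tgfbr2/Smad4 cKO, taken from the sample titles.

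The deposited table gave 1 value for each of 35556 probe sets in each array, with 0 further columns of per-sample values. These deposited values were read as log2 signals. Their unit was inferred from their range of 2.82 to 15.6, which is that of the log2 of a scanner signal, and is not stated by the labels. The software, background correction, normalization and genome build are not given in the sources used here. The columns had been made comparable before deposit, since their medians differed by at most 0.00413, so the values were used as deposited, following the rule that arrays would be normalized only if medians differed by over 0.1. Between 44.1% and 56.1% of probe sets had exactly equal values in a pair of arrays, 40.4% were equal in all 3 and 63.9% in at least 2. Such ties set many list medians to exactly 0 and narrow the range of random lists, and a small difference can be hidden by them.

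Probe sets were named through the platform annotation, which listed 23410 of them, 21789 with 1 gene symbol and 1621 with several, while 12146 were not listed and are unnamed here. Symbols were updated through the gene identifier for 21698 probe sets with a RefSeq gene table of assembly GRCm38.p6, used for names only, and kept as given for 91. Probe sets with 1 symbol were averaged per gene on the log2 scale, giving 19938 genes, of which 999 had more than 1 probe set. A gene was tested for size if its highest value over the 3 arrays was at or above the median of all values, 6.63, which 11808 genes met.

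Before the data were examined, the groups, the comparisons, the size rule of 2-fold, the level filter, 36 gene lists, the rule for named genes and the alternatives were fixed. With 1 array per group there is no test of the conditions, and no paired analysis was possible. Differences are log2 signal of one array minus that of another, for Tgfbr2 cKO minus wild type, Tgfbr2/Smad4 cKO minus wild type and Tgfbr2/Smad4 cKO minus Tgfbr2 cKO. A gene was set apart in an array if it was at least 2-fold higher, or lower, there than in both others. The lists held 926 symbols, 867 of them with a value. For each list the members at or above the level filter were counted by direction, and for lists with at least 5 such members the median difference was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins. That placement describes these arrays and tests no condition. Several lists share genes, so their results are not independent.

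The named genes were, for each comparison, the 12 with the largest difference in each direction among genes with exactly 1 probe set and an established symbol, leaving out predicted genes, small RNA genes and receptor segment families. To these were added the 8 most set apart per array and direction, Tgfbr2, Smad4, Bmp7 and the sex-linked genes, and from each list the members at least 2-fold different or, where there were none, the 2 with the largest difference. Levels of Acta2 were given as those of an abundant marker. For the 2 differences to wild type, which share a control array, 100 sets of 3 unchanged arrays were simulated.

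The alternatives were median centring, quantile normalization, cyclic loess normalization, no level filter, a filter at the 75th percentile, the probe set with the highest mean in place of the average, genes with 1 probe set only, an offset of 32 on the linear scale, and size rules of 1.5-fold and 3-fold. After the data were seen, counts were repeated with only the genes whose 3 values all differed and without the sex-linked and proliferation lists. The counting and list steps were tested on simulated data for Tgfbr2/Smad4 cKO minus wild type, with 11808 genes, a noise SD of 0.1 and 200 changed genes. They called 100% of genes changed 3-fold, 0% of genes changed 1.5-fold and 0 unchanged genes, and 3 of 100 unchanged lists fell outside the central 95%. The gene calls followed from a noise that was small beside the 2-fold rule. Simulated noise was independent between genes and made no equal values, while 36.7% of genes were equal in the real pair. The test therefore checks that the steps run as meant, not how often list calls err in these arrays. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.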

Results

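Transcript levels were measured in 3 cultured lines of mouse forestomach fibroblasts, with 1 array per line. The forestomach is the part of the rodent stomach that is lined by squamous epithelium, and the cells were selected for FSP1, a fibroblast marker encoded by S100a4. The first line was wild type. The second carried a conditional knockout (cKO) of Tgfbr2, which encodes the type II receptor for TGF-beta, and the third carried conditional knockouts of both Tgfbr2 and Smad4, which encodes the SMAD protein shared by TGF-beta and BMP signaling. Per the labels, the wild-type and Tgfbr2/Smad4 cKO lines came from normal forestomach and the Tgfbr2 cKO line came from a squamous cell carcinoma of the forestomach, so the comparison of that line with wild type differs in genotype and in tissue of origin together. The study's title asks about BMP7 signaling in stromal cells that lack the TGF-beta receptor, and the 3 lines set the labelled loss of the receptor, alone and together with that of Smad4, beside wild type without isolating either, because tissue of origin and sex pattern also differed. The 3 arrays had median log2 signals of 6.63, 6.63 and 6.63 over 35556 probe sets, and 11808 of 19938 named genes reached the median signal in at least 1 array. With 1 array per group, no difference has a replicate check, no p-value is given, and the number of arrays limits the precision of every value.

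The targeted genes came first, as a check of the labels. Tgfbr2 had log2 levels of 10.25 in the wild-type array, 10.25 in the array labelled Tgfbr2 cKO and 10.29 in the array labelled Tgfbr2/Smad4 cKO. Smad4 had levels of 11.06, 11.06 and 11.04 in the same order. In the arrays labelled as knockouts Tgfbr2 thus differed from wild type by 0 and 0.04, and Smad4 by -0.02 in the array labelled as its knockout. Each value summarised probes from exons along the whole transcript, and the removed exons could not be separated from the rest, so these values speak neither for nor against the labels. The arrays are named below as labelled. Bmp7 had a level of 6.45 in each array, under the median signal of 6.63. The sex-linked genes parted the lines. Xist, the RNA that coats the inactive X chromosome, had levels of 5.33, 5.35 and 9.44 in the wild-type, Tgfbr2 cKO and Tgfbr2/Smad4 cKO arrays. The Y-linked gene Eif2s3y had levels of 10.12, 10.00 and 5.01, Uty of 8.48, 8.44 and 5.83, and Kdm5d of 7.54, 7.73 and 5.41. The first 2 arrays thus carried a male pattern and the Tgfbr2/Smad4 cKO array a female pattern, so that array differs from the others in sex as well as genotype.

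**Figure D1:**
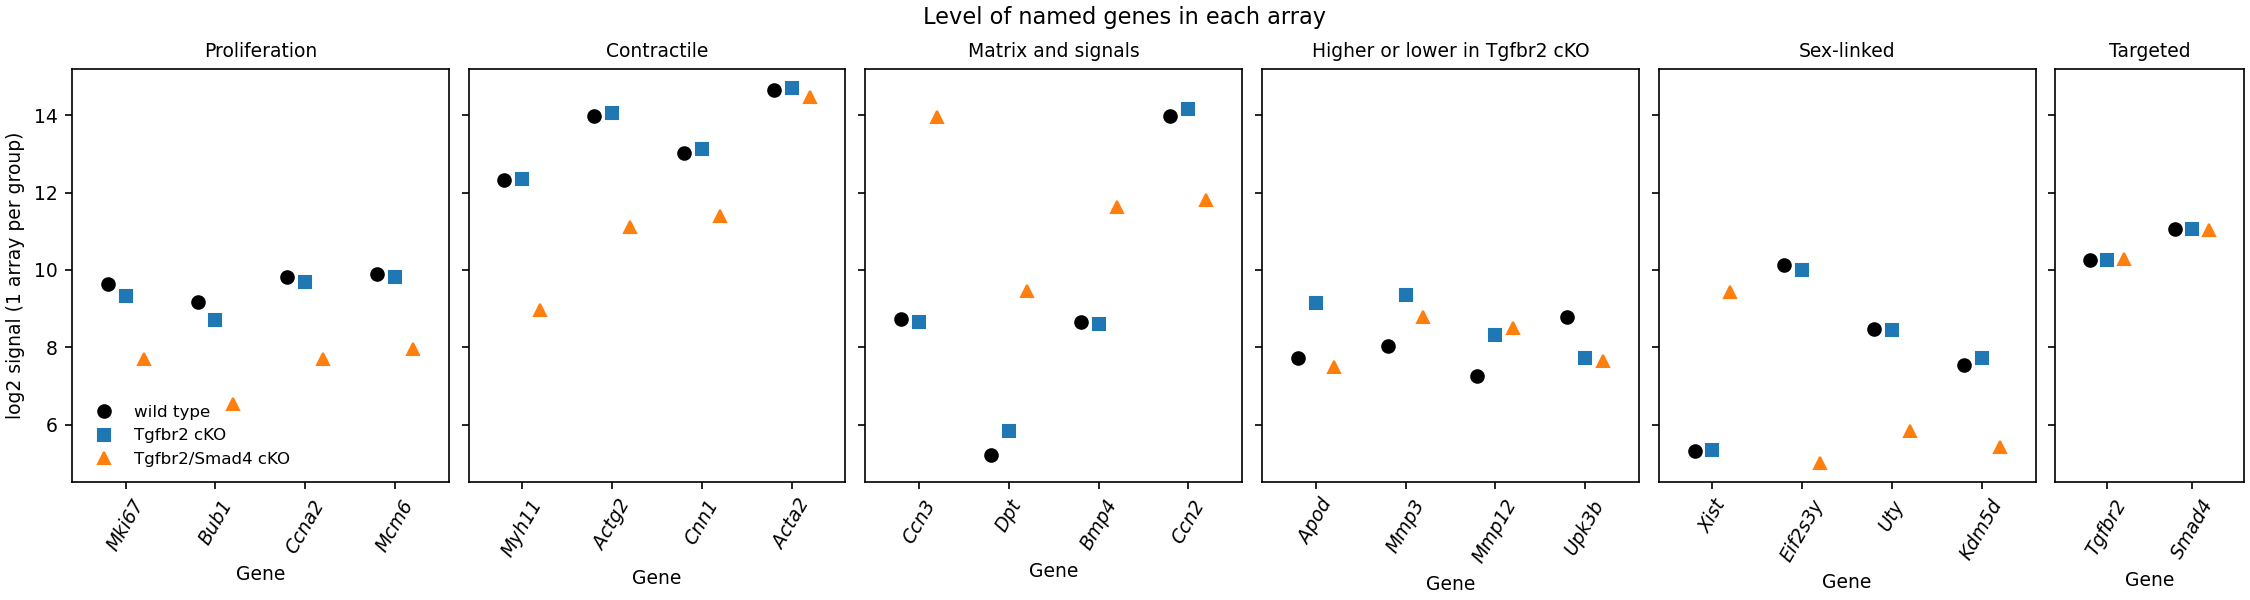
log2 signal (vertical axis) of named genes in each of the 3 arrays, with circles for wild type, squares for Tgfbr2 cKO and triangles for Tgfbr2/Smad4 cKO, 1 array each and therefore no error bars. Circles and squares lie close together for the proliferation and contractile genes, for example 12.33 and 12.36 for Myh11, while the triangle lies lower, at 8.96 for Myh11.

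The comparison of the Tgfbr2 cKO line with wild type asked how fibroblasts labelled as lacking the TGF-beta receptor differ from normal ones. Expression differed little, with 3 genes at least 2-fold higher and 1 at least 2-fold lower among 11808. Apod, which encodes the lipid-binding protein apolipoprotein D, was 1.43 higher on the log2 scale, a 2.69-fold difference. The matrix metalloproteinases Mmp3 (stromelysin 1) and Mmp12 (macrophage elastase) were higher by 1.31 and 1.08. Upk3b, a uroplakin gene used as a mesothelial marker, had a difference of -1.07. Others on the higher side were Mcpt8 at 0.996, just under 2-fold, Clca3a2 at 0.96, Pdgfrl at 0.87, Igfbp5 at 0.84 and the cytokine gene Il11 at 0.79. Others on the lower side were the glutathione transferase gene Gsta4 at -0.998, also just under 2-fold, Upk1b at -0.83, Nrn1 at -0.83, and the retinaldehyde dehydrogenase genes Aldh1a2 at -0.73 and Aldh1a1 at -0.69. The split of 3 higher to 1 lower became 3 higher to 2 lower after cyclic loess normalization, a share of 60% higher in place of 75%. The log2 differences had an SD of 0.095 over genes, and 55.1% of genes had exactly the same value in both arrays.

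Because so many values were equal, the gene lists in this comparison are described mainly by the number of members above and below 0. Proliferation genes were lower in the Tgfbr2 cKO array in 35 of 44 measured members and higher in 3, with a median of -0.16 and a largest difference of -0.47 for the mitotic checkpoint kinase gene Bub1. Hypoxia and glycolysis genes were higher in 26 of 28 and lower in 0, with a median of 0.11, led by Bnip3 at 0.45 and Ndrg1 at 0.38. Cholesterol synthesis genes were lower in 15 of 20 and higher in 0, with a median of -0.05 and a difference of -0.32 for Sqle. Of the TGF-beta target genes, 23 of 36 were higher and 5 lower, with a median of 0.03, and none differed 2-fold. The largest differences among them were 0.79 for Il11 and -0.31 for Adam12, and the connective tissue growth factor gene Ccn2 differed by 0.18. BMP target genes had a median of 0, with 5 of 26 higher, 6 lower and a largest difference of -0.28 for Msx2. Collagen genes had a median of 0.03, with 17 of 31 higher, 7 lower and a difference of 0.71 for Col14a1. Mesothelial and adipocyte markers were lower in 8 of 14 and higher in 2, with a median of -0.29. Leukocyte and macrophage markers were higher in 4 of 7 and lower in 0, with Lyz2 (lysozyme) at 0.82 and Cd68 at 0.50. Among matrix proteases, Mmp3 and Mmp12 were the members at least 2-fold higher of 31. Among inflammatory mediators, Il11 and Il6, at 0.79 and 0.71, differed most. The medians of the proliferation, hypoxia, cholesterol, TGF-beta target, collagen, mesothelial and leukocyte lists lay outside the central 95% of 10000 random lists matched on level, a narrow range here because most random medians were 0. So did those of the fibroblast, contractile, smooth muscle and immediate early lists, at 0.03, 0.04, 0.05 and 0.01, of the cell cycle inhibitor list at -0.01, and of the epithelial list at -0.08. With no level filter the leukocyte and epithelial medians were 0, at percentiles 50 and 50, and lay inside the central 95%, and the mesothelial median was -0.02 but still outside. With the filter at the 75th percentile the immediate early median was at percentile 96.5, inside the central 95%, and the epithelial median turned to 0.19, while the mesothelial and leukocyte medians were -0.55 and 0.82, these 3 over fewer than 5 members and so without a percentile. That filter also put 2 lists with a median of 0 outside the central 95%, the inflammatory mediators at -0.04 and percentile 0.16 and the Wnt pathway genes at 0.07 and percentile 99.9, and with quantile or cyclic loess normalization or median centring the medians of the growth factor, Wnt, p53 and DNA repair lists crossed that edge while staying within 0.01 of 0.

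**Figure D2:**
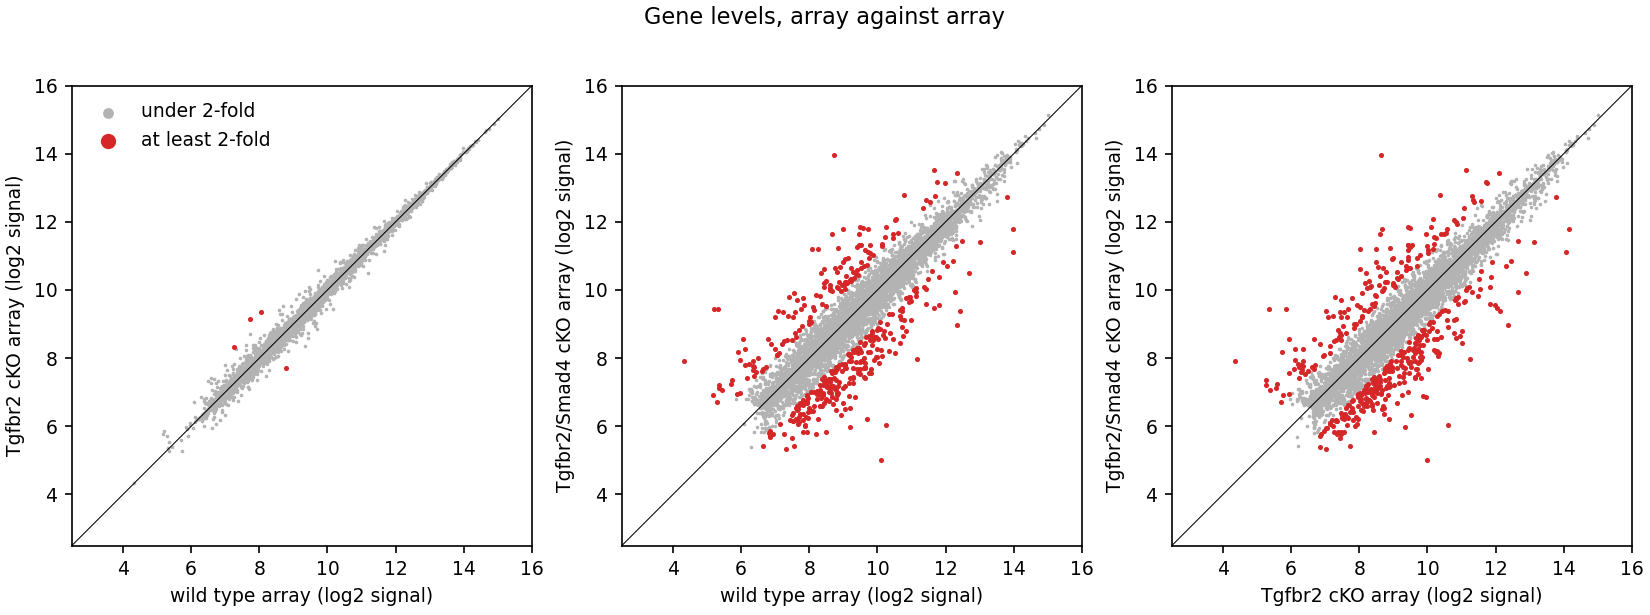
Log2 signal of each of 11808 genes in one array (horizontal axis) against another (vertical axis) for the 3 pairs of arrays, with genes at least 2-fold different in red and the line of equal signal in black. The pair of wild-type and Tgfbr2 cKO arrays shows 4 red points, against 401 and 422 in the pairs with the Tgfbr2/Smad4 cKO array.

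The comparison of the Tgfbr2/Smad4 cKO line with wild type, both from normal forestomach, showed a much wider difference. Cell cycle genes and smooth muscle contractile genes were lower, while Ccn3, Dpt, Bmp4 and several matrix genes were higher. In all, 144 genes were at least 2-fold higher and 257 at least 2-fold lower among 11808. Ccn3, a secreted matrix-associated signaling protein of the CCN family, was higher by 5.24 on the log2 scale, a 37.7-fold difference. Dpt, which encodes the matrix protein dermatopontin, was higher by 4.24 and the bone morphogenetic protein gene Bmp4 by 2.97. Others among the largest positive differences were Ifi202b at 3.60, Ecrg4 at 3.13, the potassium channel subunit gene Kcne4 at 2.93, the protease inhibitor gene Serpina3n at 2.82, Plppr4 with a 5.64-fold difference, the mTOR inhibitor gene Deptor at 2.41, Fbln7 at 2.40 and the growth arrest gene Gas1 at 2.37. The largest negative differences outside the sex-linked genes were Kcnmb1, a smooth muscle potassium channel subunit gene, at -4.21, Upk1b at -3.48, the smooth muscle myosin gene Myh11 at -3.37, Asb5 at -3.22, the peptide hormone gene Cck at -3.05, the smooth muscle actin gene Actg2 at -2.85, Bub1 at -2.64, the secreted Wnt antagonist gene Frzb at -2.59, Ptprb at -2.54 and the glycogen phosphorylase gene Pygl at -2.50.

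Proliferation genes were the most uniform group in this comparison. Of 44 measured members, 30 were at least 2-fold lower, 0 were at least 2-fold higher and 43 were below 0, with a list median of -1.25. Mki67, the source of the Ki-67 proliferation marker, had a difference of -1.94, the cyclin gene Ccna2 -2.13, the spindle motor gene Kif11 -2.31 and the replication helicase gene Mcm6 -1.95. The cell cycle inhibitor genes Cdkn2a and Cdkn2b were higher by 1.56 and 1.33, and the lamin gene Lmnb1 of the same list of 18, whose median was 0.07, had a difference of -1.35. DNA repair genes included 3 of 34 that were at least 2-fold lower, Fancb at -1.17, Chek1 at -1.13 and Pole at -1.09, and had a median of -0.06. Of 27 p53 targets, 17 were higher, with a median of 0.17, although the proapoptotic gene Pmaip1 had a difference of -1.90 and Ano3 was higher by 1.21.

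Contractile genes were lower in 17 of 20 measured members, 4 of them at least 2-fold, with a median of -0.29. These 4 were Myh11, Actg2, the intermediate filament gene Des at -2.06 and the calponin gene Cnn1 at -1.62, while the collagen-binding integrin gene Itga11 was higher by 1.54. The list of smooth muscle and pericyte markers, which shares 5 genes with it, held 5 of 14 members at least 2-fold lower and 1 higher, Notch3 at 1.18, with a median of -0.44. Acta2, the smooth muscle actin gene most used as a myofibroblast marker, differed by -0.20 from a wild-type level of 14.66. Fibroblast markers had a median of 0.19, with 5 of 19 at least 2-fold higher, among them Col6a1 at 1.81, Pdgfra at 1.40 and Fap at 1.09, and 1 lower, Thy1 at -2.36. Of 31 genes for collagens and their processing, 3 were at least 2-fold higher, Col6a1, Col6a2 at 1.38 and Pcolce at 1.12, and 1 was lower, Col14a1 at -1.30, with a median of 0.14. Among 31 matrix proteases and inhibitors, the urokinase gene Plau, Mmp10 and the urokinase receptor gene Plaur had differences of -2.04, -1.54 and -1.29, and Mmp12 and Adamts1 were higher by 1.26 and 1.16.

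TGF-beta target genes included 3 of 36 that were at least 2-fold lower, Ccn2 at -2.17, Cnn1 at -1.62 and the proteoglycan gene Vcan at -1.15, and 1 that was higher, Cdkn2b. Their median was -0.07, at percentile 1.81 of matched random lists. It was -0.052 at percentile 2.63 with no level filter and -0.052 at percentile 4.28 with the filter at the 75th percentile, both inside the central 95%. Among TGF-beta ligands, receptors and SMADs, 2 of 26 were at least 2-fold higher, the co-receptor gene Eng at 2.20 and Tgfb2 at 1.07, and the activin subunit gene Inhba had a difference of -1.36. BMP target genes had a median of 0, with 3 of 26 at least 2-fold lower, Ccn2, Id2 at -1.12 and Gata2 at -1.005, and 1 higher, Ogn at 1.60. Of 24 BMP ligands, receptors and antagonists, Bmp4 was higher by 2.97, and Gdf6, Bmper and Bmpr1b had differences of -2.23, -1.67 and -1.14.

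Of 32 genes for growth factors that stroma can supply to epithelium, 4 were at least 2-fold higher, Ptn at 1.88, Vegfd at 1.85, Wnt2 at 1.76 and Angpt2 at 1.28, and 1 was lower, Btc at -1.62. Inflammatory mediators included 3 of 18 at least 2-fold lower, Il6 at -2.28, the cyclooxygenase gene Ptgs2 at -1.07 and Vcam1 at -1.03, and 0 of 10 chemokine genes differed 2-fold. Ifi202b was the 1 of 21 interferon-stimulated genes that differed 2-fold, and the median of that list was 0.08. Hypoxia and glycolysis genes were lower in 21 of 28, with a median of -0.29, the lactate transporter gene Slc16a3 at -2.23 and, on the higher side, Eno2 at 1.10. The lists for Wnt, Notch and Hedgehog pathways had medians of 0.01, 0.06 and 0, with Dkk2 at 1.70 and Frzb at -2.59 in the first, Notch3 in the second, and Gas1 at 2.37 and Foxf2 at -1.58 in the third. Immediate early genes had a median of -0.09, with Ier3 at -1.40. Oxidative stress genes had a median of -0.07, with Gclc at -1.14. Unfolded protein response genes had a median of 0 and 0 of 24 members at least 2-fold different, and cholesterol synthesis genes a median of -0.03 and 0 of 20. Among 36 regional patterning factors, Hoxc6 was 2.30-fold higher, and Tbx18 and Foxf2 had differences of -1.59 and -1.58. Of 19 housekeeping genes, 1 differed 2-fold, the transferrin receptor gene Tfrc at -2.07.

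Markers of other cell types were given as a check of what the cultures held. Epithelial markers had a median of -0.39 over 10 members, with Krt19 at -1.89 from a wild-type level of 8.82. Mesothelial and adipocyte markers had 3 of 14 at least 2-fold lower, Upk1b, Krt19 and Upk3b at -1.14, and a median of -0.34. Leukocyte markers were lower in 4 of 7 and higher in 0, with a median of -0.25 and Lyz2 at -0.96. Endothelial markers had a median of 0 over 9 members, with Eng at 2.20 and Ptprb at -2.54. Skeletal muscle markers had a median of 0 over 12 members, with the skeletal actin gene Acta1 at -2.34, and glial and neuronal markers a median of 0.02 over 7, with Uchl1 at -1.03. The medians of the proliferation, contractile, smooth muscle, fibroblast, collagen, hypoxia, p53, epithelial, mesothelial and leukocyte lists were more than 0.1 from 0 and lay outside the central 95% of matched random lists. With no level filter the epithelial and leukocyte medians were 0, at percentiles 50 and 50, which ended both calls, and the mesothelial and smooth muscle medians were -0.12 and -0.26, still outside. With the filter at the 75th percentile the epithelial, leukocyte and mesothelial lists kept fewer than 5 members each and had no percentile. The medians of the interferon, Wnt, Notch and cell cycle inhibitor lists were also 0 with no level filter. With the filter at the 75th percentile the interferon, Wnt, Notch and Hedgehog medians were 0.32, 0.23, 0.32 and 0.26, at percentiles 99.2, 99.7, 99.1 and 99.0, the immediate early median was -0.20 and the DNA repair median was 0. The oxidative stress median, at percentile 2.83 and inside the central 95%, was -0.25 at percentile 0.01 with that filter, and also lay outside with quantile normalization, cyclic loess normalization and single probe sets, at percentiles 1.27, 2.42 and 1.59. With 32 added to each linear signal before the logarithm, the differences of Dpt, Ifi202b, Xist and Eif2s3y shrank to 3.41, 2.40, 3.33 and -4.15, since these genes were dim in 1 array of the pair.

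**Figure D3:**
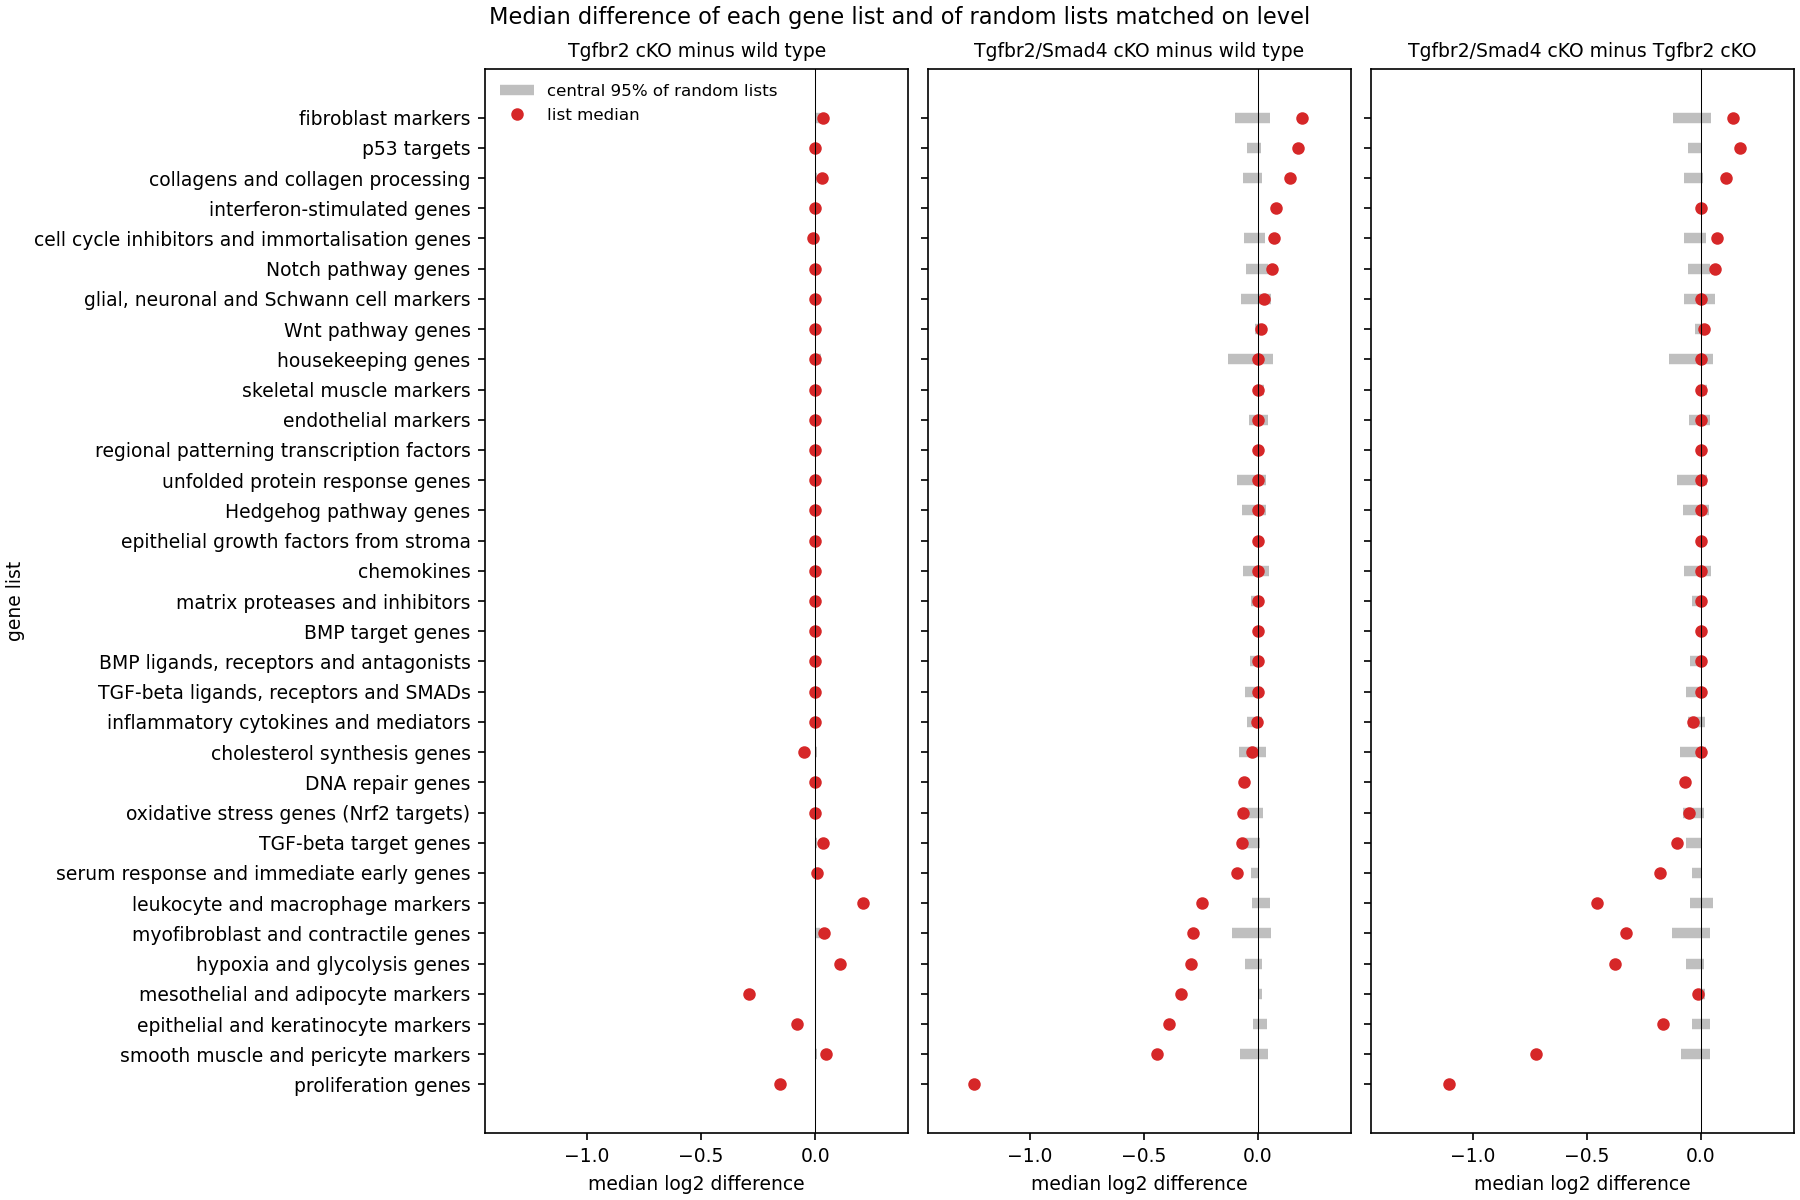
Median log2 difference of each gene list (red points, horizontal axis) beside the central 95% of 10000 random lists matched on level (grey bars) in the 3 comparisons. Proliferation genes lie at -0.16, -1.25 and -1.10, and hypoxia and glycolysis genes lie at 0.11, -0.29 and -0.38.

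The comparison of the Tgfbr2/Smad4 cKO line with the Tgfbr2 cKO line asked about the added loss of Smad4, which it does not isolate, since the lines also differed in tissue of origin and in sex pattern. Here 156 genes were at least 2-fold higher and 266 lower. Ccn3, Dpt, Serpina3n and Bmp4 were higher by 5.32, 3.60, 3.14 and 3.02, and Kcnmb1, Myh11, Asb5 and Frzb had differences of -4.57, -3.40, -3.37 and -3.18. Il6, Pygl, Igfbp5 and Il11 had differences of -2.99, -3.13, -2.42 and -1.36. Proliferation genes had 26 of 44 members at least 2-fold lower and a median of -1.10. Contractile genes had a median of -0.33 and hypoxia and glycolysis genes of -0.38. TGF-beta target genes had a median of -0.10 at percentile 0.61, with Ccn2 at -2.36. With the filter at the 75th percentile their median was -0.052 at percentile 4.58, inside the central 95%. BMP target genes had a median of 0, or -0.11 at percentile 11.3 with that filter, inside the central 95%.

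Genes set apart in a single array summarise the 3 comparisons without a common control. In the Tgfbr2/Smad4 cKO array, 124 genes were at least 2-fold higher and 221 at least 2-fold lower than in both other arrays. In the Tgfbr2 cKO array this held for Apod alone, and in the wild-type array for Upk3b, which was higher, and Mmp12, which was lower. The 2 knockout arrays therefore shared 1 gene at least 2-fold higher than wild type, Mmp12, and 1 at least 2-fold lower, Upk3b, against 0.0366 and 0.0218 for independent lists. These lists are not independent, since both subtract the same wild-type array, and no overlap was simulated for a shared control. A common direction, with a difference under 2-fold in the Tgfbr2 cKO array only, was seen for Pdgfrl at 0.87 and 2.07, Upk1b at -0.83 and -3.48, and Aldh1a2 at -0.73 and -2.41. Opposite directions were seen for Igfbp5 at 0.84 and -1.58, Il6 at 0.71 and -2.28, Col14a1 at 0.71 and -1.30, and Gsta4 at -0.998 and 0.77. Across genes, the 2 differences to wild type correlated with r = 0.0163 and had a covariance of 0.000606, and 50.3% of the genes that differed in both had the same sign. Simulated unchanged arrays with a shared control gave r = 0.501 and, with all the spread of the smaller comparison taken as noise, a covariance of 0.00453. The simulation gave all 3 arrays equal noise, which fixes its r, while the 2 differences here had SDs of 0.095 and 0.390. The r of 0.0163 therefore cannot be set against 0.501. Its covariance was likewise fixed, by the SD of 0.095 taken as noise, so 0.00453 restates that input and tests nothing. With 1 wild-type array the control could not be split, so part of any common direction may come from that array.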

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

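The test of the receptor gene and the test of smooth muscle markers were chosen after their values had been seen, as were the shuffles within level and the repeat after cyclic loess normalization, while the other tests were fixed before their results were seen. Probe sets without a gene name, which no comparison used, also differed between arrays. Of 4426 such probe sets at or above the level filter, 87 were at least 2-fold different between the Tgfbr2 cKO and wild-type arrays, 29 higher and 58 lower, a share of 1.97% against 0.0339% of named genes. Between the Tgfbr2/Smad4 cKO and wild-type arrays 147 were at least 2-fold different, 74 higher and 73 lower, a share of 3.32% against 3.40% of named genes. The log2 differences of the unnamed probe sets had SDs of 0.304 and 0.408 in these 2 comparisons, against 0.095 and 0.390 over named genes. A larger noise of unnamed probe sets could not be told apart from changed transcripts.

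The wild-type and Tgfbr2 cKO arrays were nearly alike, with 4 genes at least 2-fold different, although the lines differed in genotype and in tissue of origin. One labelled target hybridised to both arrays was taken to leave differences that probe sets of a gene do not share, but across 655 genes with more than 1 probe set the difference correlated between 2 probe sets of a gene with a Spearman value of 0.369, or 0.356 after cyclic loess normalization, against at most 0.136 when partners were shuffled among probe sets of like level. In 219 of these genes neither difference was 0. Whether probe sets of a gene overlap in sequence was not checked, so technical differences that both share are not excluded. The exactly equal values, whose origin is not given in the sources, were not the whole of the likeness either. Among 4419 genes with 3 different values the SD of the Tgfbr2/Smad4 cKO difference was 4.05 times that of the Tgfbr2 cKO difference. Its bootstrap range of 3.83 to 4.30 describes genes of these 3 arrays and not variation between lines. Joint summarising that drew the 2 arrays together without making values equal was not tested. A receptor gene that was not removed in most cells cannot be told apart from a removed one, because the Tgfbr2 difference of 0 comes from probes along the whole transcript. RNA from related cultures of 1 animal, and a small effect of the receptor in culture, were not tested and stay open.

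The Tgfbr2/Smad4 cKO array stood apart with 345 genes at least 2-fold different from both others, and hybridisation noise of that array is argued against by a Spearman value of 0.770 between probe sets of a gene across 655 genes, against at most 0.122 for partners shuffled within level. That value covers noise that differs between probe sets of a gene, not technical differences that both share. A smaller share of smooth muscle cells or pericytes, in lines labelled FSP1-positive fibroblasts, could not be decided, since 10 of 14 markers were lower than in wild type but 1, Notch3, was higher by 0.25 or more. A denser or more arrested culture with lower YAP/TEAD activity could not be decided either, because the median of 17 added YAP/TEAD target genes was 0, at percentile 56.8 of random lists, with members on both sides of 0. The test was set for targets whose values had not yet been seen, and its list did not hold Ccn2, at -2.17 in this comparison. That list was not wholly unseen, since it overlapped the fixed lists. Without the overlap the median of 16 targets was 0, at percentile 57.2. The bound fixed for that test took any median above percentile 25 as evidence against, and was set aside after the result was seen because a median of 0 among 7 members above 0, 7 below and 3 equal decides nothing. The sex of the animal, its strain mix and the genotype itself were not tested and stay open.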

How the results depend on the processing

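The repeats with only the genes whose 3 values all differed and without the sex-linked and proliferation lists were added after the data were seen, and the other alternatives were planned. Counts below are genes higher and lower, and the cause of a difference was not tested unless given. Under median centring, the highest probe set, single probe sets and both added repeats, each of the 12 counts stayed within 1.5 times its main value, with 140 higher and 242 lower for Tgfbr2/Smad4 cKO minus wild type among genes whose values all differed, and 143 and 224 without the 2 lists. For Tgfbr2 cKO minus wild type the number lower was 2 with quantile normalization and 2 with cyclic loess normalization, and 0 with the filter at the 75th percentile and 0 with the offset of 32. In the Tgfbr2 cKO array, genes set apart were 2 higher and 1 lower with quantile normalization, 1 lower with cyclic loess normalization and 2 higher with no level filter. In the wild-type array, genes set apart were 0 higher and 0 lower with the filter at the 75th percentile, which tested fewer genes, and 0 and 0 with the offset of 32, which shrinks differences of dim genes. The filter at the 75th percentile also gave 147 genes lower for Tgfbr2/Smad4 cKO minus wild type, 156 lower for Tgfbr2/Smad4 cKO minus Tgfbr2 cKO and 135 set apart as lower in the Tgfbr2/Smad4 cKO array. With a size rule of 1.5-fold, which by construction calls more genes, the counts were 25 and 19 for Tgfbr2 cKO minus wild type, 396 and 601 for Tgfbr2/Smad4 cKO minus wild type and 401 and 663 for Tgfbr2/Smad4 cKO minus Tgfbr2 cKO, with 6 and 5 set apart in the wild-type, 18 and 10 in the Tgfbr2 cKO and 345 and 550 in the Tgfbr2/Smad4 cKO array. With a size rule of 3-fold they were 0 and 0, 55 and 96, and 61 and 100, with 0 and 0 set apart in the wild-type array, 0 higher in the Tgfbr2 cKO array and 50 and 77 in the Tgfbr2/Smad4 cKO array. The median of TGF-beta target genes was -0.052 for Tgfbr2/Smad4 cKO minus wild type with no level filter and -0.052 with the filter at the 75th percentile, which also gave -0.052 for Tgfbr2/Smad4 cKO minus Tgfbr2 cKO. That filter gave a BMP target median of -0.11 for Tgfbr2/Smad4 cKO minus Tgfbr2 cKO and turned the epithelial marker median for Tgfbr2 cKO minus wild type to 0.19. Of 792 list medians under alternatives, 72 moved by over 0.1 or crossed the edge of the central 95%. A change of sign was counted only for medians outside the central 95% in the main setting, and 1 showed it. Other medians could change sign without being counted so. The glial and neuronal median for Tgfbr2/Smad4 cKO minus wild type went from 0.02 to -1.03 with the filter at the 75th percentile. That filter left the list fewer than 5 members and no percentile, and the value of -1.03 equals the difference of Uchl1 alone. Of 4716 named gene values 10 moved by over 1.5-fold. Signals near the array background, where genes are dim, limit what these differences show.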

Other observations

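The genes in this paragraph were chosen after their values were seen, and their signs in Tgfbr2/Smad4 cKO minus wild type were kept under median centring, quantile and cyclic loess normalization. No list of complement, iron, metallothionein or flavin monooxygenase genes was fixed or tested, so the values stand for single genes. In Tgfbr2/Smad4 cKO minus wild type, the complement genes C1ra, C1s1, Cfb and C4b were higher by 1.98, 1.86, 1.55 and 0.71 and the C1 inhibitor gene Serping1 by 1.54, while Cd55, which encodes a regulator that protects cells from complement, had a difference of -1.98. The lipopolysaccharide-binding protein gene Lbp was higher by 2.07. In Tgfbr2 cKO minus wild type, C1ra, C1s1, Cfb, C4b, Serping1, Cd55 and Lbp differed by 0.14, -0.03, -0.01, 0.40, 0.26, -0.30 and -0.19. In Tgfbr2/Smad4 cKO minus wild type, the iron importer gene Tfrc had a difference of -2.07, the iron exporter gene Slc40a1 of 2.21, the iron reductase gene Steap3 of 2.17, the heme oxygenase gene Hmox1 of -0.59 and the ferritin heavy chain gene Fth1 of 0.01. The metallothionein genes Mt2 and Mt1 had differences of -2.20 and -1.06, and the flavin monooxygenase genes Fmo2 and Fmo1 were higher by 2.31 and 2.15. Beside the Xist difference of 4.11, the X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x, known to escape X inactivation, had differences of 1.02, 0.61, 0.53 and 0.14.

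The tests on added mesothelial markers were fixed before their results were seen, while the naming of Msln and Wt1, the repeat without genes of the fixed lists and the demand that both versions agree were chosen after. Of the mesothelial markers, 4 that were lower in both knockout arrays were Upk3b at -1.07 and -1.14, Upk1b at -0.83 and -3.48, Msln at -0.46 and -0.52 and Wt1 at -0.41 and -0.41 in the Tgfbr2 cKO and Tgfbr2/Smad4 cKO arrays. They were picked from a fixed list of mesothelial and adipocyte markers that was not uniform. In the Tgfbr2 cKO array 8 of its 14 measured members were lower, 4 equal and 2 higher, with Krt19 higher at 0.42. In the Tgfbr2/Smad4 cKO array 10 were lower, 2 equal and 2 higher. A smaller share of mesothelial cells, in lines labelled FSP1-positive fibroblasts, is a candidate explanation, and over 13 further markers the list median was 0 in both comparisons, at percentiles 49.2 and 49.6 of random lists, with 5 members exactly equal in each and the rest on both sides of 0, among them in the Tgfbr2/Smad4 cKO array Cd200 and Efemp1, at least 2-fold higher at 1.76 and 1.08, and Tm4sf1 at -1.05. Some of these markers were not wholly unseen, since they also belong to the fixed lists, and without them the median of 11 markers was 0 in the Tgfbr2 cKO comparison, at percentile 48.5, but -0.12 in the Tgfbr2/Smad4 cKO comparison, at percentile 2.04, with 6 lower, 2 higher and 3 equal. The bounds fixed beforehand took a median below percentile 2.5 as evidence for a smaller share and one above percentile 25 as evidence against. For the Tgfbr2/Smad4 cKO culture the 11 markers met the first bound and the 13 markers the second. As the versions disagreed, that culture was left undecided, under the demand for agreement chosen after. For both cultures the bound of 25 was set aside after the result, because a median of 0 with members on both sides of 0 decides nothing. Neither culture can thus be told apart from one in which these genes were lower within the fibroblasts. Genotype stays open as well, as do tissue of origin for the Tgfbr2 cKO array and sex for the Tgfbr2/Smad4 cKO array, which were not tested.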
